A study of Mus musculus with 19 samples.

How the data were processed

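The deposited data hold RNA sequencing of 19 mouse placentas, 1 library per placenta. According to the labels, C57BL/6J dams received pooled HEamiRNAs, a mixture of microRNAs, or scrambled microRNA as control by tail vein on gestational day 10. The part of the placenta outside the decidua, the maternal layer, was dissected on gestational day 18. Total RNA was depleted of ribosomal RNA, turned into stranded libraries and sequenced in pairs of reads on an Illumina NovaSeq. Per the labels, the submitters' steps named Trimmomatic, HISAT2, HTSeq and DESeq2 without versions, and the genome build mm10.

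For each library the authors deposited HTSeq counts for 25239 gene symbols. The counts were whole numbers, summed to between 39864554 and 61371498 per library and were used for every test. The deposited table of normalized signal equalled the counts divided by 1 size factor per column, with a largest relative deviation of 5.08e-10. The authors also deposited 1 DESeq2 result table with the mean normalized signal, the log2 fold change with its standard error on the log2 scale, the Wald score, the p-value and the adjusted p-value of each gene. The sign of its fold changes followed HEamiRNA over control, and its model was not stated. No rows of unassigned reads and no mitochondrially encoded genes were present, so the shares of mapped and mitochondrial reads are unknown.

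The annotation, feature type and strand setting behind the counts were not stated. Gene positions were taken from GENCODE release M21, whose symbols matched 24366 of the 25239 rows (96.5%). Of 505 small RNA genes inside an intron of another gene on the same strand, 481 had a count of 0 in every library (95.3%). The share was 67.2% of 67 such genes on the opposite strand and 45.4% of 326 genes outside other genes. Mean counts were 31558 for Xist and 150 for Tsix, its antisense transcript. Judged by the small RNA genes, a count may include reads from introns, and a gene's value may cover its whole transcribed region. This was not settled. Reads assigned to none of the genes are missing from the totals. Counting error was small at these totals, and intervals for counting error cover neither duplicates from amplification nor the spread between animals.

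Groups came from the labels: 4 control males, 5 control females, 6 HEamiRNA males and 4 HEamiRNA females. The replicate number named the dam within a treatment, giving 5 control and 6 HEamiRNA dams, of which 8 gave 1 placenta of each sex. After group means were taken out, log2 profiles of placentas from 1 dam had a median correlation across genes of 0.187 (8 pairs), against -0.159 for different dams of the same treatment (73 pairs). Taking out group means by itself lowers correlations within a group. Many of the 73 pairs lay within 1 group and none of the 8 did, so the contrast is partly built in. Genes are not independent replicates, so these correlations carry no p. Control and HEamiRNA dams with equal numbers are different animals and were not treated as pairs.

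Genes were tested with the edgeR (version 4.0.16) quasi-likelihood F test in R 4.3.3, with TMM normalization, low-count genes removed by filterByExpr, and Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p under 0.05. A model of the 4 group means gave the treatment effect in males, in females, their difference (males minus females, the interaction), and the sex difference within controls and within HEamiRNA placentas (17206 genes). Another model used counts summed per dam, since the dam was injected, with the share of male placentas as a covariate (17550 genes). Its fold changes hold at equal male share and can differ from ratios of the printed group means. Only control dam 2 gave no male, and only HEamiRNA dams 2 and 5 gave no female. The male share is therefore partly confounded with the treatment, and its slope rests on these dams. The fitted treatment effect rests mainly on the dams that gave both sexes. In the comparisons, CPM, counts scaled to a common library total, use TMM-scaled totals; Xist, the Y-linked sums and the search for single-library jumps use plain totals. Group values are means ± SD of CPM. Fold changes are log2 values with their standard error (SE).

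Before the data were examined, 30 gene lists were fixed: syncytiotrophoblast, trophoblast giant cells, spongiotrophoblast and glycogen cells, decidual stroma, natural killer and cytotoxic cells, macrophages, neutrophils, erythroid cells, endothelium, angiogenic signalling, smooth muscle and pericytes, epithelial-mesenchymal transition, extracellular matrix, yolk sac endoderm, stratified epithelium and amnion, interferon response, inflammatory cytokines, hypoxia response, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, cell cycle, nutrient transporters, imprinted genes, unfolded protein and stress response, cholesterol synthesis, immediate early genes, Y-linked genes, and X inactivation and escape. Some genes stand in more than 1 list. Of these lists 29 had at least 4 tested genes and were tested. The mitochondrially encoded list had none. The list test was camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the 29 lists of each comparison. Camera with an estimated correlation, the rotation test fry and an exact two-sided permutation test of each list's mean log2 CPM (prior count 2) were run beside it. Per dam this permutation test compared the dam scores directly, without the male share as a covariate.

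Named genes followed a rule fixed beforehand. Where no gene passed, the 5 genes per direction with the smallest p were given as values that did not pass, among genes with a mean of at least 1 CPM in a group and no predicted or clone name. Up to 4 members with the smallest p were named from each list that passed. Always named were Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Hba-a1, Hbb-bt, Prl8a2, Tpbpa, Prl3b1, Afp, Cdh1, Vim, Vegfa, Flt1 and Pgf. Hba-a1 and Hbb-bt did not pass the low-count filter and were not tested. Other genes of the authors' table were chosen after their values were seen.

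The pipeline was tested on simulated counts of 17206 or 17550 genes with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 3-fold. In the male, female and per-dam comparisons it recovered 46.3%, 49.3% and 50.7% of the genes changed 1.5-fold, and 91.0%, 70.1% and 79.1% of those changed 2-fold. For the interaction these shares were 28.4% and 62.7%. False calls numbered 7 to 13 per comparison. The simulated counts were drawn independently for each gene and library, without a shared effect of the dam or correlation between genes. These shares may therefore not hold for the real data.

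Alternatives included DESeq2 1.42.0, limma voom with quality weights or with the dam as a random effect, other scalings and filters, a replicate block, and leaving out each library or dam. Chosen after seeing the data were fits without the libraries whose sex-linked counts went against their labels, a yolk sac covariate, the permutation of list scores, the alternatives for the lists of the sex comparisons, exact sign-flip tests of list scores within dams, and refits of the authors' table. Up to 100 other splits of the samples were fitted for each comparison with a fixed seed, and 60 for the refit of the authors' model. Figures and correlations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the comparisons described first.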

Results

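Expression was measured in 19 placentas of mice whose dams had received HEamiRNAs or scrambled microRNA, a control sequence with no intended target, on gestational day 10. There were 4 control males, 5 control females, 6 HEamiRNA males and 4 HEamiRNA females from 11 dams. Library totals were 40829796 to 61371498 counts in control males, 46333850 to 58551744 in control females, 43021089 to 60295076 in HEamiRNA males and 39864554 to 59515764 in HEamiRNA females. Between 19113 and 19924 genes had at least 1 count in a library.

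The sex labels were compared with Xist, the RNA that silences 1 X chromosome in female cells (chromosome X, 103460366 to 103483254), and with the sum of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. In 8 libraries labelled male, Xist was at 193 ± 74.2 CPM and the Y-linked sum at 186 ± 16.6 CPM (SD, n = 8). In 6 libraries labelled female the values were 1103 ± 67.0 and 0.183 ± 0.169 CPM (SD, n = 6). In all, 3 libraries lay on the other side of their label. The library labelled Control Female 3 had a Y-linked sum of 157 CPM and Xist at 174 CPM, and that labelled HEamiRNA Female 3 had 164 and 168 CPM. The library labelled HEamiRNA Male 3 had a Y-linked sum of 0.0354 CPM and Xist at 1170 CPM. The library labelled Control Male 3 had both signals, with Y-linked counts at 69.9% of the labelled-male median and Xist at 46.2% of the labelled-female median. HEamiRNA Female 1 had Xist at 1253 CPM and Y-linked counts at 10.4% of the labelled-male median. All libraries kept their labels below, and fits without them were run as alternatives.

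**Figure D1:**
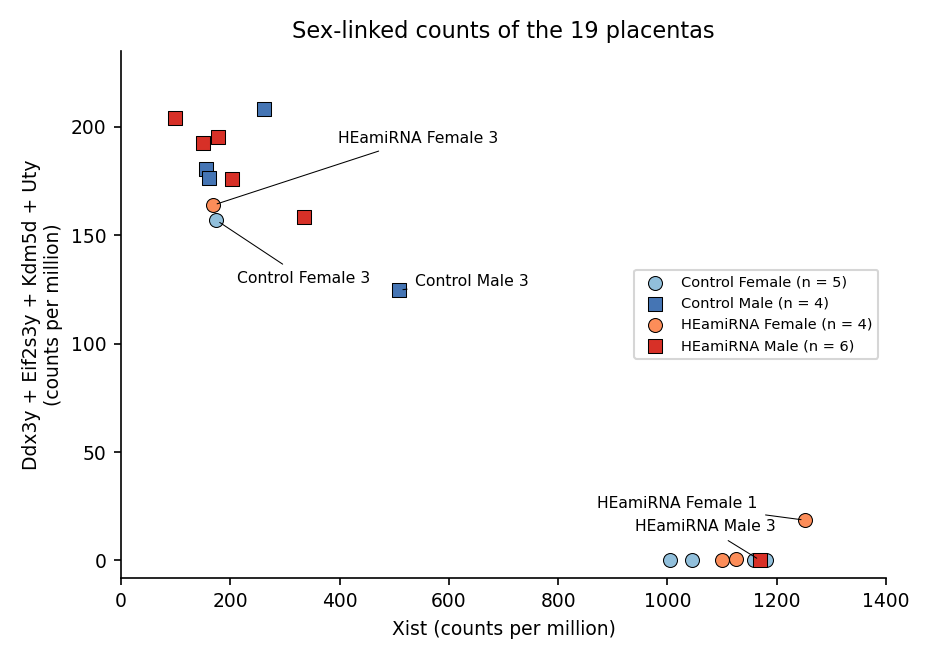
Xist (x axis) against the sum of 4 Y-linked genes (y axis), both in CPM, with 1 point per placenta, coloured by labelled group. The 3 libraries labelled Control Female 3, HEamiRNA Female 3 and HEamiRNA Male 3 lie among points of the other label, and the library labelled Control Male 3 lies between the clusters.

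The treatment effect was first asked per dam, the animal that was injected (6 HEamiRNA against 5 control dams). Placentas of HEamiRNA dams had higher values of glycolysis enzymes and of syncytiotrophoblast, endothelial and angiogenic genes, and lower values of yolk sac endoderm and interferon genes, by camera with the preset correlation only. The adjusted p was 0.000512 for syncytiotrophoblast, 1.40e-05 for glycolysis, 0.00202 for angiogenic signalling, 0.000616 for endothelium, 0.000668 for hypoxia, 2.23e-05 for yolk sac endoderm and 0.000616 for interferon response. With an estimated correlation none of these lists passed (adjusted p = 0.403 for syncytiotrophoblast and angiogenic signalling, 0.421 for glycolysis and hypoxia, 0.442 for endothelium and interferon response, 0.474 for yolk sac endoderm). Exact permutation tests compared the list scores of all 11 dams without the male-share covariate, while the covariate fit leaned on the dams that gave both sexes. In these exact tests the differences of log2 scores were 0.16 for syncytiotrophoblast (p = 0.0758), 0.0690 for glycolysis (0.279), 0.0312 for angiogenic signalling (0.444), 0.0611 for endothelium (0.346), 0.0224 for hypoxia (0.716), -0.28 for yolk sac endoderm (0.513) and -0.0620 for interferon response (0.258), all smaller than the means of the covariate fit given below. The syncytiotrophoblast is the fused trophoblast layer that carries nutrient and gas exchange. Its 12 listed genes averaged a log2 fold change of 0.24, with 10 higher and 2 lower. Synb, which encodes syncytin-B, a fusion protein of that layer (chromosome 14, 69289344 to 69294299), had 7.09 ± 2.84 CPM in HEamiRNA dams against 2.85 ± 0.782 CPM in control dams (log2 1.5, SE 0.342). Gcm1, a transcription factor needed for syncytiotrophoblast formation, had a log2 fold change of 0.43 (SE 0.194), Dlx3 of 0.35 (SE 0.142) and the lactate transporter gene Slc16a3 of 0.21 (SE 0.0795). All 15 glycolysis genes were higher, by a mean log2 of 0.13, with Pgam1, the phosphoglycerate mutase gene, at 36.0 ± 2.63 against 32.0 ± 2.36 CPM (log2 0.23, SE 0.0688).

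Of 28 angiogenic signalling genes, 19 were higher and 9 lower per dam (mean log2 0.08). The Notch pathway genes Hey1 (0.64, SE 0.160) and Dll4 (0.35, SE 0.0981), the ephrin gene Efnb2 (0.21, SE 0.0829) and Vegfb (0.36, SE 0.164) had the smallest p among them. Endothelium markers were higher for 15 of 17 genes (mean log2 0.12), with Sox17 at 0.31 (SE 0.157) and Sox18 at 0.44 (SE 0.226). The hypoxia response list had a mean log2 of 0.10, with 17 of 21 genes higher, among them Ankrd37 (0.73, SE 0.213) and Hk2 (0.23, SE 0.0879). Ankrd37 was at 4.58, 3.52 and 5.52 CPM in HEamiRNA dams 1, 3 and 4. HEamiRNA dams 2, 5 and 6 (2.37 to 2.50) lay within the controls (2.05 to 3.93), as did dam 3. Yolk sac endoderm genes, many of which encode secreted plasma proteins, were lower for all 16 members (mean log2 -0.49), with Fga at -0.74 (SE 0.482) and Apoa1 at -0.65 (SE 0.456). Interferon response genes were lower for 24 of 26 members (mean -0.11), with Usp18 at -0.30 (SE 0.0886). In the fits that left out 1 dam these 7 lists kept their call with the preset correlation, in 11 of 11 fits. The yolk sac endoderm mean ranged from -1.07 (without HEamiRNA dam 6) to -0.20 (without control dam 4) in them, the endothelium mean was 0.0677 without control dam 3 and the hypoxia mean 0.0637 without HEamiRNA dam 4. Without the 3 libraries against their sex label the hypoxia list no longer passed (mean 0.0631), and the glycolysis mean was 0.0694.

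Another 11 lists passed the same test per dam, and none with an estimated correlation (adjusted p 0.442 for erythroid cells to 0.715 for ribosomal proteins). Higher were erythroid cells (mean log2 0.26, 13 of 14 genes), immediate early genes (0.37, 13 of 14), natural killer and cytotoxic cells (0.41, 9 of 9), nutrient transporters (0.06, 19 of 23) and imprinted genes (0.07, 18 of 26). Lower were cholesterol synthesis (-0.15, 17 of 20 genes), stratified epithelium and amnion (-0.71, 8 of 9), extracellular matrix (-0.20, 19 of 24), macrophages (-0.15, 12 of 14), ribosomal proteins (-0.06, 42 of 54) and oxidative phosphorylation (-0.05, 38 of 46). Examples were the granzyme gene Gzmf at 0.51 (SE 0.313), Fosb at 1.96 (SE 0.613), the amino acid transporter gene Slc7a5 at 0.27 (SE 0.116), Dlk1 at 0.23 (SE 0.135), Dsg3 at -1.45 (SE 0.617), C1qc at -0.32 (SE 0.135), Fbn1 at -0.33 (SE 0.162), Msmo1 at -0.27 (SE 0.147), Slc4a1 at 0.38 (SE 0.262), Rpl22 at -0.18 (SE 0.0843) and Ndufb3 at -0.18 (SE 0.0798). The Fosb value rested on HEamiRNA dams 1 and 6, at 39.1 and 34.4 CPM, since the other 4 HEamiRNA dams (3.69 to 6.24) lay near the controls (4.8 to 6.39). Gzmf was highest in HEamiRNA dam 4 (10.8 CPM, other HEamiRNA dams 3.55 to 6.70, controls 2.40 to 6.70). Each of these calls ended without at least 1 dam: control dam 1 (stratified epithelium, extracellular matrix, macrophages, ribosomal proteins), control dam 3 (erythroid, nutrient transporters, imprinted), control dam 4 (cholesterol), HEamiRNA dam 1 (immediate early, macrophages, ribosomal, oxidative phosphorylation), HEamiRNA dam 3 (macrophages), HEamiRNA dam 4 (natural killer, extracellular matrix) or HEamiRNA dam 6 (immediate early, nutrient transporters, imprinted, ribosomal, oxidative phosphorylation). The extracellular matrix mean turned to 0.00476 without control dam 1, and the ribosomal mean to 0.0134 without HEamiRNA dam 1. In these fits the means nearest 0 were 0.0953 for erythroid cells, 0.157 for immediate early genes, 0.126 for natural killer cells, 0.0119 for nutrient transporters, 0.0246 for imprinted genes, -0.0569 for cholesterol synthesis, -0.37 for stratified epithelium, -0.0298 for macrophages and -0.00878 for oxidative phosphorylation. Natural killer cells (mean 0.25) and stratified epithelium (-0.61) no longer passed without the 3 libraries against their sex label. Exact permutation tests without the covariate gave 0.19 for erythroid (p = 0.327), 0.13 for immediate early (0.610), 0.13 for natural killer (0.643) and 0.0279 for nutrient transporters (0.621). They gave 0.0433 for imprinted genes (0.455), -0.0159 for cholesterol (0.913), -0.18 for stratified epithelium (0.693) and -0.17 for extracellular matrix (0.323). The rest were -0.15 for macrophages (0.171), -0.0640 for ribosomal (0.431) and -0.0379 for oxidative phosphorylation (0.392).

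Lists that did not pass per dam included epithelial-mesenchymal transition (mean log2 -0.07, 20 of 32 genes lower), cell cycle (-0.04), trophoblast giant cells (0.01), spongiotrophoblast and glycogen cells (0.02), decidual stroma (0.00), smooth muscle and pericytes (-0.21), unfolded protein and stress response (0.04), inflammatory cytokines (-0.05), neutrophils (-0.13), Y-linked genes (-0.30), and X inactivation and escape (0.10). The trophoblast marker gene Tpbpa (log2 0.00, SE 0.165) and the trophoblast hormone gene Prl3b1 (0.03, SE 0.107) did not pass. The prolactin family gene Prl8a2 (-0.28, SE 0.311) did not pass either, nor did the angiogenic factors Vegfa (0.15, SE 0.106), Flt1 (0.16, SE 0.168) and Pgf (0.04, SE 0.154). The adhesion gene Cdh1 was at -0.19 (SE 0.192), Vim, an intermediate filament gene of mesenchymal cells, at -0.18 (SE 0.0984), and Afp at -0.51 (SE 0.428). Xist was at 0.35 (SE 0.281). Without the male-share covariate the differences of dam scores had the opposite sign for Y-linked genes (1.98) and for X inactivation and escape (-0.18).

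No single gene passed per dam with the edgeR quasi-likelihood test, whose smallest adjusted p was 0.979. An unadjusted p under 0.05 was found for 688 of 17550 genes (chance gives 877.5), and DESeq2 on the same summed counts called 1 gene, Synb (log2 1.51, adjusted p 0.0457). Adjusted over the list alone, 1 list member passed, again Synb. The Synb values of HEamiRNA and control dams overlapped. HEamiRNA Female 1, whose sex-linked counts were intermediate, had 15.8 CPM, and the other HEamiRNA females had 4.50 to 5.39. Among genes with at least 1 CPM, the 5 higher genes with the smallest p were Prelid2 (log2 0.51, SE 0.112), Ldlrad3 (0.33, SE 0.0747), Synb, the endothelial transcription factor gene Sox7 (0.59, SE 0.135) and Glt1d1 (0.71, SE 0.164). Among those lower they were Serpinb8 (-0.56, SE 0.127), the interleukin 36 receptor gene Il1rl2 (-0.55, SE 0.126), the integrin gene Itgb6 (-0.53, SE 0.121), Npsr1 (-0.66, SE 0.160) and the hyaluronan receptor gene Cd44 (-0.37, SE 0.0900). Sox7 was at 7.42 ± 1.24 against 5.27 ± 0.614 CPM, and Il1rl2 at 4.85 ± 0.538 against 7.03 ± 0.975 CPM (SD, 6 and 5 dams).

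**Figure D2:**
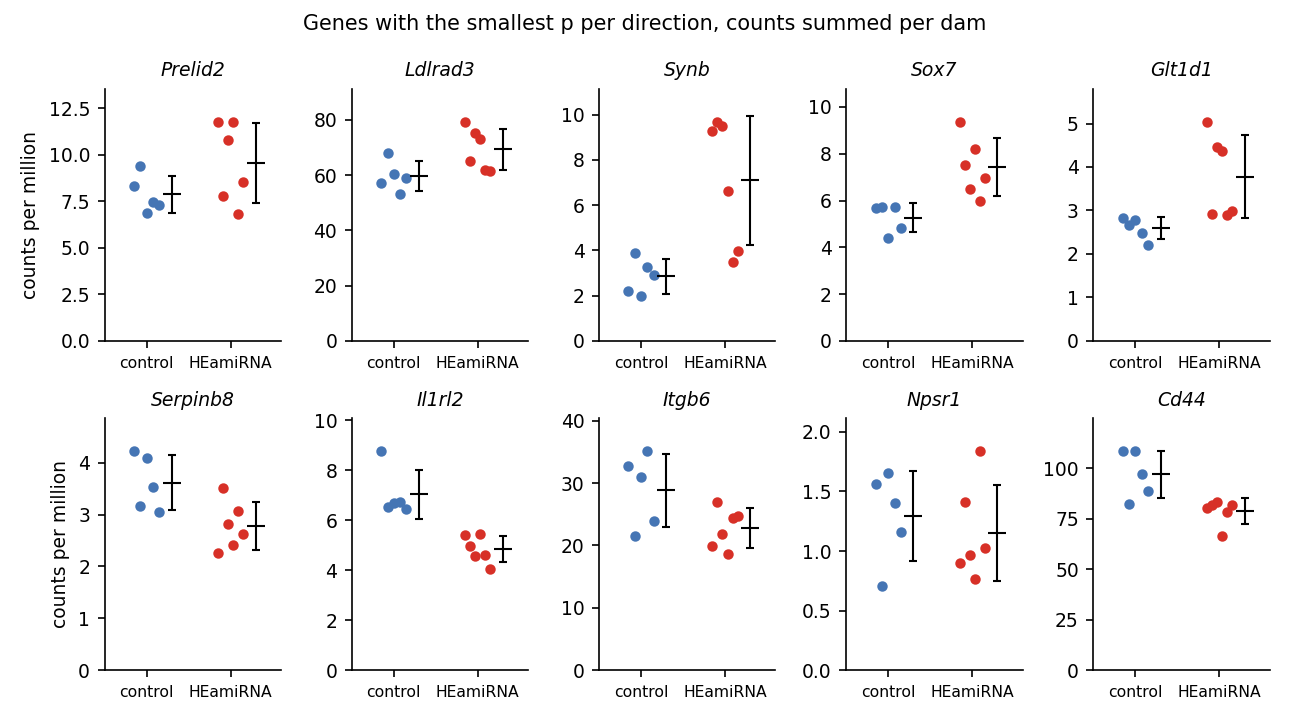
CPM (y axis, from 0) of 10 genes, the 5 per direction with the smallest p, with 1 point per dam (5 control, 6 HEamiRNA) and the mean ± SD beside the points. None passed the edgeR test after adjustment, and the spread within groups can be seen for Synb, with means of 2.85 and 7.09 CPM.

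In males (6 HEamiRNA against 4 controls), genes of red blood cell precursors were higher in HEamiRNA placentas by camera with the preset correlation only. All 13 tested erythroid genes were higher, by a mean log2 of 0.48 (camera adjusted p 1.18e-07). With an estimated correlation the adjusted p was 0.551. Erythroid genes included the globin genes Hba-a2, at 6.74 ± 2.05 against 3.62 ± 0.999 CPM (log2 0.90, SE 0.315; chromosome 11, 32296489 to 32297298), and Hba-x (1.26, SE 0.435), the anion exchanger gene Slc4a1 (0.67, SE 0.276) and Alas2, the first enzyme of heme synthesis in red cells (0.55, SE 0.252). Both globin genes had low counts, with Hba-x at 0.157 to 0.691 CPM over the dams. Hba-a1 and Hbb-bt fell under the low-count filter, so these values may not measure globin RNA as a whole. The call of the erythroid list with the preset correlation was kept in all 10 fits that left out 1 library. The exact permutation test of the list score gave p = 0.00476, adjusted p = 0.138 (n = 6 and 4). A p of 0.00476 is the smallest that the 210 splits can give, so 1 list alone could not pass after adjustment.

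A further 12 lists passed camera in males with the preset correlation. None passed with an estimated one (adjusted p 0.783 for cell cycle, cholesterol synthesis and yolk sac endoderm and 0.558 for the other 9). Higher lists were syncytiotrophoblast (mean log2 0.24, 10 of 12 genes), endothelium (0.13, 14 of 17), glycolysis (0.10, 14 of 15), nutrient transporters (0.07, 19 of 23), imprinted genes (0.09, 18 of 25), cell cycle (0.11, 21 of 28) and angiogenic signalling (0.07, 20 of 28). Examples were Synb (1.36, SE 0.457), Slc7a5 (0.34, SE 0.130), the glucose transporter gene Slc2a1 (0.16, SE 0.0698), Zdbf2 (0.19, SE 0.0898), Dll4 (0.27, SE 0.109), Robo4 (0.28, SE 0.140), Pgam1 (0.23, SE 0.0714) and Top2a (0.43, SE 0.286). Lower lists were epithelial-mesenchymal transition (mean log2 -0.10, 23 of 32 genes), extracellular matrix (-0.17, 22 of 24), decidual stroma (-0.17, 8 of 8), cholesterol synthesis (-0.11, 17 of 20) and yolk sac endoderm (-0.38, 16 of 16). The transition list holds epithelial and mesenchymal genes, and its members with the smallest p were the matrix protease genes Mmp14 (-0.23, SE 0.0829) and Mmp9 (-0.52, SE 0.241), Vim (-0.28, SE 0.109) and Tgfb2 (-0.31, SE 0.140). Others were the laminin gene Lama4 (-0.32, SE 0.119), Hand2, a transcription factor of the decidual stroma (-0.38, SE 0.164), Nsdhl (-0.15, SE 0.0895) and Fga (-0.62, SE 0.585). Of these 12 lists, the transition list passed in all 10 fits that left out 1 library (mean -0.0635 without Control Male 4), and the others lost their call in at least 1. Calls ended without Control Male 1 (extracellular matrix, mean 0.0493; nutrient transporters, 0.0414; syncytiotrophoblast), Control Male 3 (imprinted genes, 0.0523; syncytiotrophoblast), Control Male 4 (cholesterol, -0.018; yolk sac, -0.0832; endothelium), Control Male 5 (decidual stroma), HEamiRNA Male 2 (decidual stroma, -0.0454), HEamiRNA Male 4 (glycolysis, 0.0364) and HEamiRNA Male 5 (cholesterol, yolk sac). For cell cycle and angiogenic signalling they ended in 6 of 10 fits each (means 0.0549 to 0.171 and 0.0615 to 0.111). Cell cycle (0.12) and cholesterol synthesis (-0.0858) no longer passed without the 3 libraries against their sex label. Exact permutation tests of the scores of these 12 lists gave p = 0.00952 for imprinted genes (adjusted 0.138). For the rest p ran from 0.0714 for syncytiotrophoblast to 0.457 for extracellular matrix.

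No gene passed in males with edgeR (smallest adjusted p 0.993) or with DESeq2, and 718 of 17206 genes had an unadjusted p under 0.05 (chance gives 860.3). No member passed when adjusted over the list alone. The smallest p among higher genes belonged to Uhrf1, which maintains DNA methylation (log2 0.40, SE 0.0928; 6.24 ± 0.568 against 4.74 ± 0.476 CPM), Mex3d (0.41, SE 0.102), Hoxa13 (0.60, SE 0.151), Nt5dc2 (0.39, SE 0.1) and Exoc3l2 (0.62, SE 0.159). Among lower genes they were Kap (-1.79, SE 0.416; 0.447 ± 0.215 against 1.56 ± 1.02 CPM), Tma16 (-0.37, SE 0.0916), the metalloproteinase gene Tll1 (-0.78, SE 0.199), Pnoc (-1.25, SE 0.319) and AW112010 (-0.50, SE 0.130). Log2 fold changes of Afp (-0.40, SE 0.536), Cdh1 (-0.03, SE 0.242), Vegfa (0.08, SE 0.122), Flt1 (0.05, SE 0.219), Pgf (0.03, SE 0.241), Prl3b1 (0.06, SE 0.153), Prl8a2 (-0.29, SE 0.3) and Tpbpa (-0.04, SE 0.236) did not pass.

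In females (4 HEamiRNA against 5 controls), macrophage genes and yolk sac endoderm genes were lower in HEamiRNA placentas by camera with the preset correlation only. With an estimated correlation the adjusted p was 0.655 for both lists. Of 14 macrophage genes 12 were lower (mean log2 -0.29, camera adjusted p 0.000275), including the 3 complement genes C1qa (-0.60, SE 0.203; 4.68 ± 0.888 against 7.09 ± 2.08 CPM), C1qb (-0.47, SE 0.174) and C1qc (-0.51, SE 0.167), and Tyrobp (-0.56, SE 0.216). All 16 yolk sac endoderm genes were lower (mean -0.58, adjusted p 1.63e-05), with Alb at -1.51 (SE 0.904; 159 CPM in HEamiRNA Female 6, 10.3 to 21.8 in the other 3 and 57.5 to 326 in controls) and Rbp4 at -0.49 (SE 0.334). With the preset correlation both calls were kept in all 9 fits that left out 1 library, although the yolk sac mean ranged from -1.73 to -0.27 in them, with the lower end reached without HEamiRNA Female 6 and the upper without Control Female 1. The macrophage mean was -0.159 without Control Female 1. The exact permutation test of the list scores gave p = 0.175 for macrophages and 0.238 for yolk sac endoderm (n = 4 and 5).

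Another 13 lists passed camera in females with the preset correlation. None did with an estimated one (adjusted p 0.724 for ribosomal proteins, spongiotrophoblast and cholesterol synthesis and 0.655 for the other 10). Higher were glycolysis (mean log2 0.12, 15 of 15 genes), natural killer and cytotoxic cells (0.47, 9 of 9), immediate early genes (0.31, 12 of 14), spongiotrophoblast and glycogen cells (0.15, 22 of 26), hypoxia response (0.06, 16 of 21) and Y-linked genes (0.74, 4 of 4). Lower were stratified epithelium and amnion (-0.92, 8 of 9 genes), cell cycle (-0.16, 23 of 28), ribosomal proteins (-0.07, 44 of 54), oxidative phosphorylation (-0.05, 37 of 46), interferon response (-0.10, 23 of 26), extracellular matrix (-0.25, 15 of 24) and cholesterol synthesis (-0.12, 16 of 20). Examples were Gzmf (0.75, SE 0.414), Fosb (1.78, SE 0.706), Hk2 (0.22, SE 0.103), Pcdh12 (0.20, SE 0.126), Krt6a (-1.90, SE 0.979), Mcm6 (-0.18, SE 0.0918), Usp18 (-0.27, SE 0.112), Fbn1 (-0.39, SE 0.171), Hmgcr (-0.32, SE 0.200), Rpl13 (-0.14, SE 0.0830) and Sdhb (-0.13, SE 0.0697). The Fosb value rested on HEamiRNA Female 1 and 6, at 29.3 and 30.8 CPM, while HEamiRNA Female 3 and 4 (5.58 and 6.65) lay near the controls (5.06 to 5.59). Krt6a stood at 18.7 and 26.6 CPM in Control Female 1 and 4 and at 0.646 to 6.05 CPM in the other 7. Each of the 13 calls ended in at least 1 fit that left out a library. Without the library labelled HEamiRNA Female 3 the calls of glycolysis (mean 0.0398), cell cycle (-0.0623), hypoxia (0.0213), stratified epithelium and extracellular matrix ended. The same omission turned the means of spongiotrophoblast (-0.17) and of Y-linked genes (-2.30), and the ribosomal mean turned to 0.0279 without HEamiRNA Female 1. Other means moved to 0.124 for immediate early genes and -0.00772 for oxidative phosphorylation (without HEamiRNA Female 1), 0.20 for natural killer cells (without HEamiRNA Female 4), and -0.0477 for cholesterol synthesis, -0.0965 for extracellular matrix and -0.61 for stratified epithelium (without Control Female 1). Glycolysis (0.0503), hypoxia (0.0313) and spongiotrophoblast (-0.0363) no longer passed without the 3 libraries against their sex label. Exact permutation tests of the scores of these 13 lists gave p from 0.222 for immediate early genes to 0.762 for spongiotrophoblast.

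No gene passed in females with edgeR (smallest adjusted p 0.935) or with DESeq2, and 748 genes had an unadjusted p under 0.05 (chance gives 860.3). No member passed when adjusted over the list alone. Among higher genes the smallest p belonged to Polg2, a subunit of the mitochondrial DNA polymerase (log2 0.44, SE 0.0944; 10.5 ± 1.0 against 7.68 ± 0.660 CPM), H2-Q4 (0.36, SE 0.0867), Smtn (0.36, SE 0.0874), the nuclear export gene Xpo1 (0.23, SE 0.0558) and the phosphodiesterase gene Pde4b (0.44, SE 0.108). Among lower genes they were the kinase gene Map3k8 (-0.26, SE 0.0587), Jarid2, a cofactor of Polycomb repression (-0.57, SE 0.147; 316 ± 26.8 against 469 ± 85.9 CPM), Lrrc3b (-1.0, SE 0.271), Fhl2 (-0.36, SE 0.0989) and Dnah7b (-0.75, SE 0.214). Without the 5 libraries with doubtful sex-linked counts 1 gene passed, Mgat2 (log2 1.17, adjusted p 0.0232), in a fit of 2 HEamiRNA against 4 control females. Mgat2 was named after its value was seen and lies near the 7SL RNA genes, where single libraries stood far above the others (Mgat2 at 585 CPM in HEamiRNA Male 3, others 37.7 to 124). Afp (-0.57, SE 0.567), Cdh1 (-0.36, SE 0.253), Vim (-0.16, SE 0.114), Vegfa (0.19, SE 0.126), Flt1 (0.31, SE 0.227), Pgf (0.06, SE 0.250), Prl3b1 (0.08, SE 0.159), Prl8a2 (-0.35, SE 0.315) and Tpbpa (0.14, SE 0.245) did not pass.

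**Figure D3:**
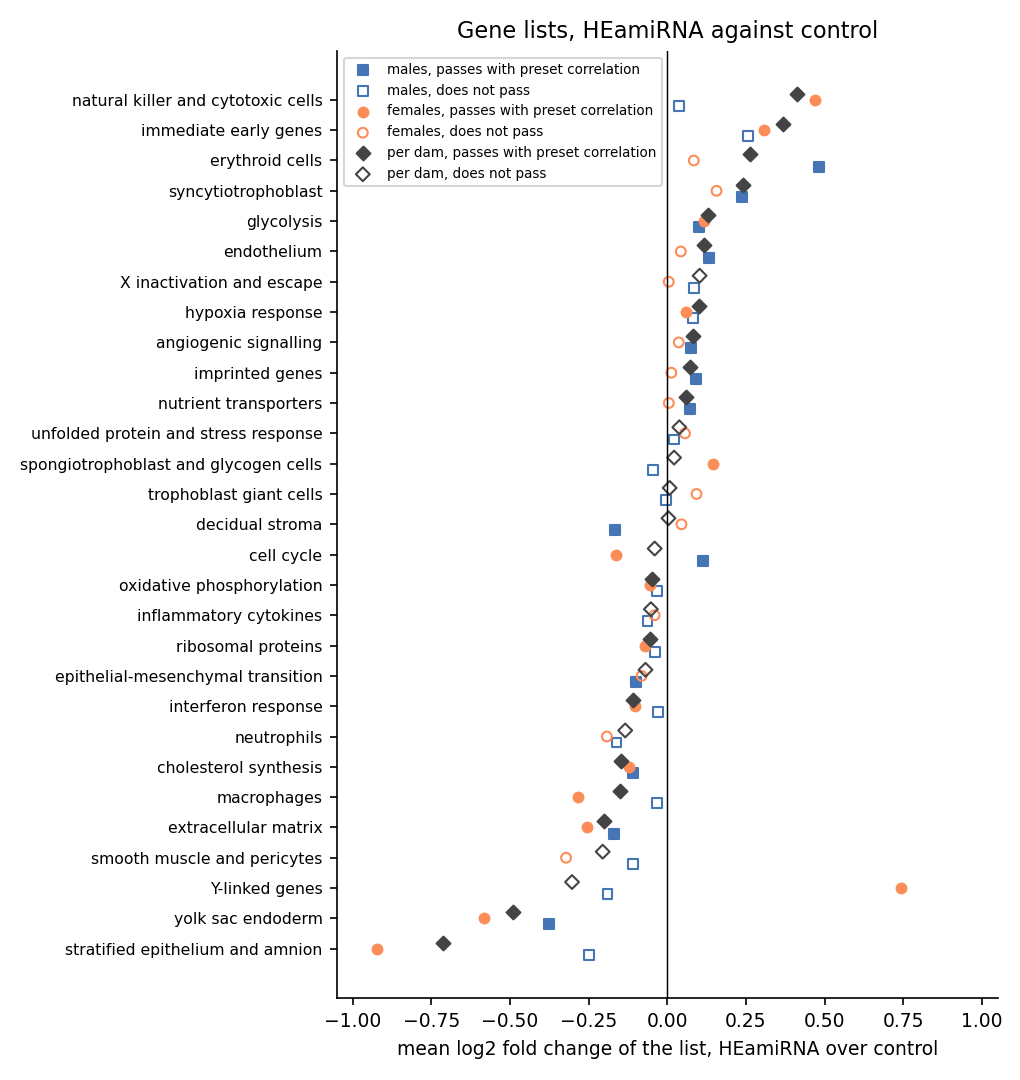
Mean log2 fold change (x axis, HEamiRNA over control) of the members of each of 29 lists in males, in females and per dam. Filled symbols passed camera with the preset correlation, and none passed with an estimated one. Yolk sac endoderm lies at -0.38, -0.58 and -0.49, and erythroid cells lie at 0.48, 0.08 and 0.26.

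**Figure D4:**
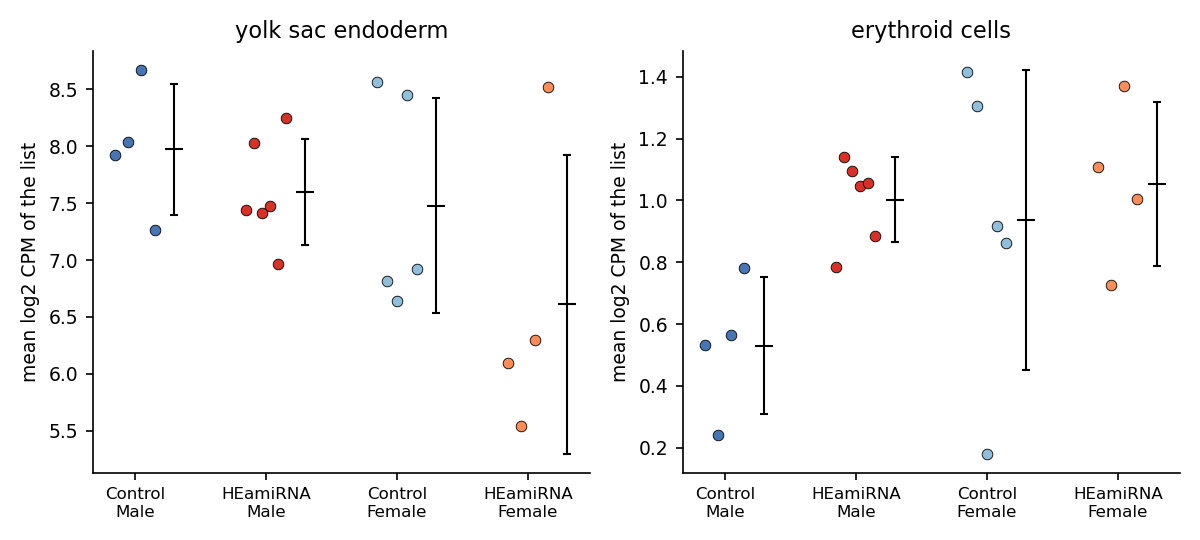
Mean log2 CPM (y axis) of the yolk sac endoderm and erythroid lists in each placenta, by labelled group, with the mean ± SD beside the points. The erythroid score averaged 0.53 in 4 control males and 1.00 in 6 HEamiRNA males, and the yolk sac scores of the groups overlap.

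Whether the treatment effect differed between the sexes was tested as the effect in males minus that in females. Cell cycle genes had a higher effect in males than in females for 24 of 28 members (mean log2 0.28, camera adjusted p 2.58e-06), among them the mitotic genes Bub1 (0.73, SE 0.341), Kif11 (0.64, SE 0.308) and Top2a (0.77, SE 0.411). With an estimated correlation neither this list nor the 5 others that passed did so (adjusted p 0.940 for spongiotrophoblast and 0.776 for the other 5). The difference was also positive for erythroid cells (0.40, 12 of 13 genes, Hba-a2 0.80, SE 0.445) and macrophages (0.25, 11 of 14, C1qa 0.60, SE 0.280). It was negative for decidual stroma (-0.21, 7 of 8, Esr1 -0.53, SE 0.251), spongiotrophoblast and glycogen cells (-0.19, 23 of 26, Prl7b1 -0.59, SE 0.326) and Y-linked genes (-0.93, 4 of 4). The cell cycle call was kept in all 19 fits that left out 1 library (mean 0.179 without HEamiRNA Female 3). Calls of the others ended without HEamiRNA Female 3 (spongiotrophoblast at 0.13 and Y-linked at 2.11), HEamiRNA Male 3 (Y-linked), HEamiRNA Male 2 (decidual, mean -0.0846) or Female 4 (decidual), Control Female 1 (erythroid 0.26, macrophages 0.131, spongiotrophoblast), Control Male 5 (macrophages), or Control Male 1 or 3 (spongiotrophoblast). The spongiotrophoblast list no longer passed (mean -0.0101) without the 3 libraries against their sex label. With the dam as a replicate block, spongiotrophoblast (-0.0724) and decidual stroma (-0.0456) no longer passed, and the cell cycle mean was 0.14. The erythroid mean was 0.22 in that fit. Yolk sac endoderm (0.71), ribosomal proteins (0.0777), natural killer cells (-0.40) and immediate early genes (0.15) newly passed there with the preset correlation. With the block and an estimated correlation none of these passed (adjusted p 0.918).

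No gene passed the interaction test with edgeR (smallest adjusted p 0.9998) or with DESeq2, and 239 genes had an unadjusted p under 0.05 (chance gives 860.3). No member passed when adjusted over the list alone. The smallest p among positive differences belonged to Uhrf1 (0.55, SE 0.133), Dok3 (0.83, SE 0.272), Yrdc (0.26, SE 0.0887), Snrpa (0.23, SE 0.0804) and Arhgef39 (0.66, SE 0.232). Among negative ones they were Gadd45a, induced by DNA damage (-0.51, SE 0.156), Sh3gl3 (-0.74, SE 0.241), the relaxin family receptor gene Rxfp2 (-1.45, SE 0.480), H2-Q4 (-0.36, SE 0.120) and Pnoc (-1.39, SE 0.472). With the dam as a replicate block, on dams that gave both sexes, 0 genes passed.

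The sexes were compared within each treatment, in 4 males and 5 females among controls and 6 males and 4 females among HEamiRNA placentas. The labelled groups include the 3 libraries against their sex label. Camera with the preset correlation passed 16 lists in controls and 6 in HEamiRNA placentas. Once the correlation was estimated none passed, with adjusted p = 0.273 and 0.291 for cholesterol synthesis, 0.565 and 0.434 for yolk sac endoderm, 0.220 and 0.132 for X inactivation and escape, 0.136 and 0.571 for Y-linked genes, and 0.254 for erythroid cells in controls. With the preset correlation only, cholesterol synthesis genes were higher in males in both treatments, for 19 of 20 genes each (mean log2 0.25 in controls and 0.26 in HEamiRNA placentas). Insig1 was at 0.37 (SE 0.131) and 0.30 (SE 0.128), Cyp51 at 0.35 (SE 0.134) and 0.29 (SE 0.131), and Dhcr7 at 0.24 (SE 0.0853) and 0.20 (SE 0.0828). Yolk sac endoderm genes were higher in males for 16 of 16 genes in both (0.33 and 0.54). Over the dams, cholesterol synthesis scores were highest (4.67 to 4.82) where yolk sac scores were highest (8.03 to 8.59), in control dams 1 and 4 and HEamiRNA dams 2 and 6. The list of X inactivation and escape genes was lower in males (-0.48 in controls, -0.40 in HEamiRNA placentas), with Kdm5c at -0.29 (SE 0.104) and -0.23 (SE 0.0990). Erythroid genes were lower in control males than in control females for 12 of 13 genes (-0.48), and in HEamiRNA placentas the mean was -0.08 and did not pass. Y-linked genes had a mean of 2.56 in controls and 1.63 in HEamiRNA placentas. In fits without the 3 libraries against their sex label, means in controls and HEamiRNA placentas were 0.19 and 0.27 for cholesterol synthesis, -0.58 and -0.70 for X inactivation and escape, and 11.09 and 4.93 for Y-linked genes, and -0.63 for erythroid cells in controls. The yolk sac mean was then 0.15 in controls, where the list no longer passed, and 0.29 in HEamiRNA placentas. In fits that left out 1 library, the yolk sac call in controls ended without Control Female 3 (mean 0.147) or Control Male 4 (0.0325), and its mean was 0.163 and 0.185 without Control Female 2 or 5 and 0.64, 0.58 and 0.52 without Control Female 1, Control Female 4 or Control Male 5. In HEamiRNA placentas the yolk sac mean ranged from 0.245 without HEamiRNA Female 3 to 1.68 without HEamiRNA Female 6, with 0.31, 0.35 and 0.35 without HEamiRNA Female 1, Female 4 or Male 6. The Y-linked call in HEamiRNA placentas ended without HEamiRNA Female 4 or 6 (means 1.21), and Y-linked means were 11.08 without Control Female 3 and 4.66 without HEamiRNA Female 3. Cholesterol synthesis means moved to 0.152 without Control Male 4 and 0.42 without HEamiRNA Female 6, and the X inactivation mean to -0.62 without HEamiRNA Male 3. Apart from those said to have ended, the calls named here were kept with the preset correlation.

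The sexes were also compared within the 8 dams that gave 1 placenta of each, 4 per treatment, a test chosen after the data were seen. The cholesterol synthesis score was higher in the placenta labelled male in 7 of 8 dams (mean difference 0.25 ± 0.21, SD, exact sign-flip permutation p = 0.0156, adjusted over 29 lists 0.388). Among its genes, Cyp51 and Dhcr7 were higher in 8 of 8 dams and Insig1 in 7 of 8, for Cyp51 from 25.6 against 24.3 CPM in control dam 5 to 31.1 against 20.2 CPM in control dam 3. The yolk sac endoderm score was also higher in the labelled male in 6 of 8 dams (0.68 ± 0.90, exact sign-flip permutation p = 0.0859, adjusted 0.388). The largest cholesterol differences, 0.51, 0.49 and 0.42 in control dam 3 and HEamiRNA dams 1 and 4, came with yolk sac differences of 1.40, 1.34 and 1.18. HEamiRNA dam 3 had 0.22 and 1.88. Whether the 2 lists differ separately was not tested. The 8 dams include control dam 3 and HEamiRNA dam 3, which hold the 3 libraries against their sex label. In HEamiRNA dam 3 the Y-linked sum was 0.0354 CPM in the labelled male and 164 CPM in the labelled female. In control dam 3 it was 125 CPM in the labelled male and 157 CPM in the labelled female. The counts out of 8 dams follow the labels, so neither of these dams can be read as a male higher than a female. In the other 6 dams the cholesterol difference was 0.21 ± 0.21 (5 of 6 higher, exact permutation p = 0.0625, adjusted 0.181). Cyp51 and Dhcr7 were higher in the labelled male in 6 of these 6 dams and Insig1 in 5 of 6. There the X inactivation and escape (-0.66), erythroid (-0.35) and cell cycle (-0.17) scores were lower in the labelled male in 6 of 6 dams, with exact permutation p = 0.0312, the smallest that 6 dams can give, and adjusted p = 0.181. No list passed this test after adjustment. Compared between the labelled groups, without regard to the dam, exact permutation of the cholesterol scores gave p = 0.127 in controls and 0.0571 in HEamiRNA placentas. With the dam as a replicate block and the preset correlation, camera passed 18 lists in controls and 9 in HEamiRNA placentas, and with the block and an estimated correlation 0 in both (adjusted p 0.502 and 0.452 for cholesterol synthesis). In the blocked fit Y-linked genes no longer passed in HEamiRNA placentas (mean 3.93), and the yolk sac mean there was 1.04.

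With all libraries under their labels, no gene passed with edgeR or DESeq2 in controls (smallest adjusted p 0.999) or in HEamiRNA placentas (0.9997). Genes with an unadjusted p under 0.05 numbered 433 and 211. Ddx3y was at 2.40 (SE 1.6) and 1.67 (SE 1.6), Eif2s3y at 3.18 (SE 1.51) and 1.42 (SE 1.44), Kdm5d at 2.26 (SE 1.5) and 1.71 (SE 1.52), Uty at 2.42 (SE 1.65) and 1.72 (SE 1.65), and Xist at -1.71 (SE 0.720) and -1.34 (SE 0.652). Without the 3 libraries whose Y-linked counts went against their label, 8 genes passed in controls, 7 of them higher in males, and 13 in HEamiRNA placentas, 7 of them higher in males. The fitted log2 values of Ddx3y were then 12.87 in controls and 4.76 in HEamiRNA placentas (adjusted p 0.000257 and 0.0312), and Xist in HEamiRNA placentas was at -2.56 (adjusted p 0.0184). Such values against libraries near 0 counts depend on the prior count and are no bounds. Adjusted over the list alone, 4 members of the X inactivation and escape list passed in controls with all libraries, all lower in males. With the dam as a replicate block, 0 genes passed in controls and 3 in HEamiRNA placentas, Hsd3b1 (2.20), Kcnmb2 (1.90) and Sftpd (2.07).

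The genes with the smallest p in controls were Pnoc (1.20, SE 0.333), Adgra1 (0.70, SE 0.195), Tma16 (0.33, SE 0.0954), Vmn2r122 (0.67, SE 0.197) and Nppb (0.66, SE 0.204) among those higher in males. Among those lower they were Ttbk1 (-0.48, SE 0.130), Ltk (-0.46, SE 0.139), Dnaaf1 (-1.08, SE 0.327), the cation channel gene Trpm2 (-2.24, SE 0.688) and Kifc1 (-0.53, SE 0.170). In HEamiRNA placentas they were Rnf212b (0.84, SE 0.271), Klhdc2 (2.77, SE 0.930), Faap24 (0.31, SE 0.105), Zfp959 (0.39, SE 0.133) and the Y-linked Zfy1 (3.98, SE 1.38), and, lower in males, Zfp775 (-0.32, SE 0.101), Hoxb4 (-0.46, SE 0.148), the X-linked O-GlcNAc transferase gene Ogt (-0.39, SE 0.132), Ttc39aos1 (-0.24, SE 0.0841) and Inafm2 (-0.15, SE 0.0539). The Klhdc2 value rested on 1 library, labelled HEamiRNA Male 1.

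The authors' deposited DESeq2 table called 42 genes at an adjusted p under 0.05, 27 higher and 15 lower with HEamiRNAs, and gave the smallest adjusted p as 0.00127. Lower in that table were Jarid2 (authors' log2 -0.43, SE 0.0826), Tll1 (-0.47, SE 0.0975), Il1rl2 (-0.43, SE 0.0911), the macrophage scavenger receptor gene Msr1 (-0.32, SE 0.0821) and Mmp19 (-0.41, SE 0.101). Higher were Polg2 (0.33, SE 0.0619), Sox7 (0.43, SE 0.0865), Synb (0.40, SE 0.0963), and the Notch pathway genes Hey1 (0.39, SE 0.0953), Dll4 (0.28, SE 0.0693) and Rfng (0.25, SE 0.0629). A refit with DESeq2 of sex plus treatment over 19 placentas, with a coefficient prior, called the same 42 genes, with log2 fold changes within 0.00486 of the table. In that model the placentas of a dam count as independent samples. Without the 3 libraries whose sex-linked counts went against their label, the refit called 79 genes, of which 29 were among the 42. Synb was not called in that refit (adjusted p 0.0700). With treatment alone in the model, on all 19 placentas, it called 16 genes (8 higher, 8 lower), all 16 among the 42.

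Per dam the smallest adjusted p of the 42 genes with edgeR was 0.979, and DESeq2 on counts summed per dam called 1 of them, Synb. The 42 genes were selected on these same placentas, so their equal sign per dam and in both sexes is no separate evidence. The edgeR test of sex plus treatment on the 19 placentas called 0 genes. Over all genes tested, the values of the 6 HEamiRNA dams and the 5 control dams did not overlap for 0.296% of genes, where chance gives 0.433%. Across 17550 genes, which are not independent replicates, the authors' fold changes and those per dam, both from the same libraries, had a Pearson correlation of 0.794. Of the 42 genes, 4 stood in a list fixed beforehand.

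**Figure D5:**
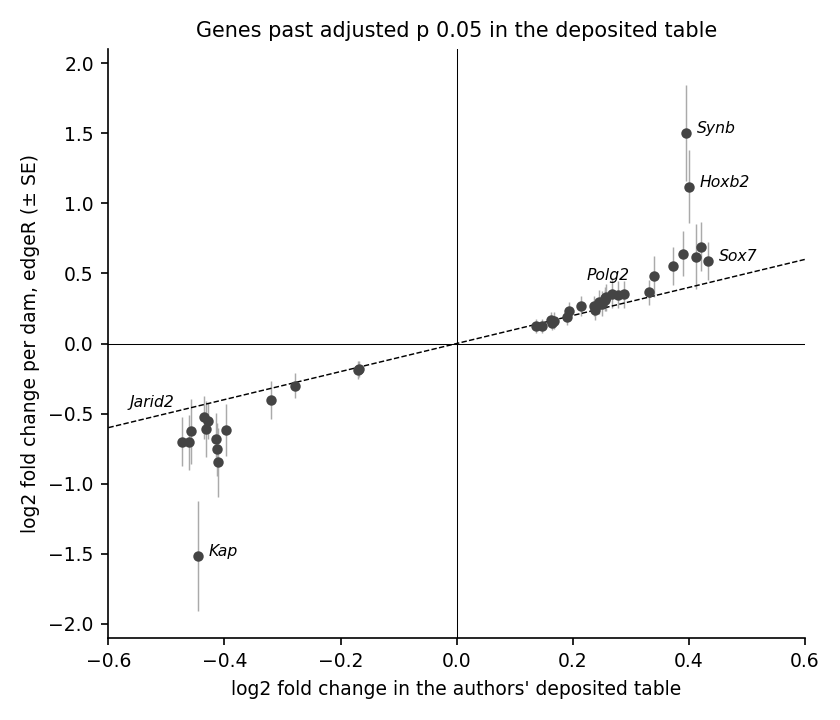
Log2 fold change in the authors' deposited table (x axis) against the edgeR log2 fold change per dam with its SE (y axis) for the 42 genes past adjusted p 0.05 in that table. The dashed line marks equal values. All 42 points lie in the quadrants of equal sign, as genes selected on the same placentas tend to, and Synb lies at 0.40 and 1.5.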

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

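The tests on splits for gene counts and for the lists of the sex comparisons, on counts per dam and edgeR for the authors' genes, on exchanged placentas, and on yolk sac tissue and spread between dams were chosen after the results were seen.

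The sex-linked counts of 3 libraries lay far from the others of their labelled group. Y-linked counts were 156.9 CPM in Control Female 3 (others 0.0372 to 0.129), 163.8 CPM in HEamiRNA Female 3 (others 0.302 to 18.6) and 0.0354 CPM in HEamiRNA Male 3 (others 158.5 to 204). Xist was at 174 CPM (others 1005 to 1180), 168.4 CPM (others 1100 to 1253) and 1170 CPM (others 97.9 to 335) in the same libraries. The score of X inactivation and escape genes was 7.15 in Control Female 3 (others 7.83 to 7.96) and 7.31 in HEamiRNA Female 3 (others 7.85 to 7.89). Ogt, which is X-linked, was at 311.5 CPM in HEamiRNA Male 3 (others 193 to 228) and at 242 CPM in Control Male 3 (others 198 to 201).

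For control dam 3, an exchange of its 2 placentas was argued against, since the placenta labelled male kept Y-linked counts at 69.9% of the labelled-male median, where an exchanged female would be near 0. For HEamiRNA dam 3, both placentas (2 of 2) were out of place in opposite directions, so an exchange of their labels may explain this pair. In Control Male 3, the share of XX cells worked out from the missing Y-linked counts was 33.1% and from Xist 34.7% (difference 1.56 percentage points, 2 SD 24.2), so RNA of XX cells in this sample is a candidate explanation. This test excluded little, since HEamiRNA Male 6 gave 16.7% and 17.4% and Control Male 5 met the bound with -13.6% and 8.6% (difference 22.2, 2 SD 23.2). The label of Control Female 3 and the Y-linked counts of HEamiRNA Female 1 stay open, and no biological explanation was tested.

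Other libraries far from their group were found for named genes. In HEamiRNA Female 3, CPM were 93.3 for Fhl2 (others 80.0 to 82.1), 8256 for Prl3b1 (4986 to 5331) and 10670 for Tpbpa (4529 to 5210). Its scores were 4.59 for syncytiotrophoblast (5.23 to 5.31), 0.160 for neutrophils (0.792 to 0.837), 4.69 for endothelium (5.18 to 5.25), 3.95 for angiogenic signalling (4.29 to 4.35) and 6.52 for unfolded protein and stress response (6.02 to 6.04). In Control Male 5, CPM were 1989 for Flt1 (2930 to 3077), 11.8 for Gadd45a (9.19 to 9.62), 1.18 for Pnoc (1.67 to 1.73), 4910 for Prl3b1 (6052 to 6234) and 5.45 for Uhrf1 (4.46 to 4.54). In HEamiRNA Female 1, they were 1.12 for Pnoc (0.626 to 0.656), 15.8 for Synb (4.50 to 5.39) and 10.6 for Yrdc (9.52 to 9.61). In HEamiRNA Female 6, Afp was at 11330 CPM (1528 to 2349) and Jarid2 at 355.8 CPM (299 to 306).

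Single genes were also far from the others in other libraries: Adgra1 at 2.27 CPM in HEamiRNA Male 3 (others 1.44 to 1.66), Arhgef39 at 2.05 and Dnah7b at 14.2 in Control Female 4 (2.89 to 3.22 and 7.07 to 8.29), Hoxa13 at 1.11 in Control Male 3 (1.66 to 1.73), and Jarid2 at 581.9 and Vegfa at 103 in Control Male 4 (394 to 420 and 77.0 to 81.2). Klhdc2 was at 1427 and Ltk at 2.54 CPM in HEamiRNA Male 1 (41.4 to 79.7 and 3.06 to 3.36), Prelid2 at 8.64 in Control Male 1 (7.11 to 7.29), Prl8a2 at 237 in HEamiRNA Male 2 (722 to 846), Rnf212b at 1.93 in HEamiRNA Male 5 (0.845 to 1.20), Trpm2 at 22.6 in Control Female 1 (4.38 to 9.63) and Zfp959 at 4.64 in HEamiRNA Male 6 (3.34 to 3.77). Scores were 5.19 for decidual stroma in HEamiRNA Male 2 (5.98 to 6.35), 2.32 for natural killer and cytotoxic cells (1.11 to 1.44) and 6.27 for glycolysis (5.83 to 5.99) in HEamiRNA Male 4, and 5.97 for smooth muscle and pericytes in Control Male 1 (4.76 to 4.87). Of 376 groups examined, 45 held such a library, where chance gives 18.8. HEamiRNA Female 3 accounted for 11 of the 45.

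The treatment effect differed between males and females (males minus females) for 6 lists by the camera test of the interaction: cell cycle 0.28, erythroid cells 0.40, macrophages 0.25, decidual stroma -0.21, spongiotrophoblast and glycogen cells -0.19 and Y-linked genes -0.93. None passed with an estimated correlation. Of 70 splits of the samples, 55 gave as many lists, with 20 at most, so chance cannot be excluded. For single genes the real split gave 0 with edgeR, a count that all 70 splits must reach (0 at most in the others), so nothing about chance follows, with 239 genes at an unadjusted p under 0.05 and 0 called by DESeq2.

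Chance could also not be excluded for the number of lists in the other treatment comparisons. In males 22 of 100 splits gave at least the 13 lists found (highest other 18), in females 21 of 100 gave at least the 15 found (highest other 21), and per dam 8 of 100 gave at least the 18 found (highest other 20). For sex in HEamiRNA placentas 90 of 100 splits gave at least the 6 lists found (highest other 18), so chance cannot be excluded there either. For sex in controls 4 of 100 splits gave at least the 16 found (highest other 18), a share narrowly under 5%. Most of these splits put both placentas of some dams on 1 side, unlike the real split. This share therefore cannot exclude chance for that number. The 12 other splits of controls that parted as many pairs from 1 dam gave at most 14 lists, and the 6 such splits of HEamiRNA placentas at most 15, too few splits for a share under 5%. For genes, edgeR called 0 in the 5 comparisons other than the interaction. All 100 splits must give at least 0, so the splits say nothing about chance there. Unadjusted p under 0.05 numbered 718, 748, 688, 433 and 211 for males, females, dams, controls and HEamiRNA placentas, and DESeq2 called 1 gene per dam and 0 in the other 4. The highest other split called 0 genes in males, 800 in females, 1 per dam, 182 for sex in controls and 356 for sex in HEamiRNA placentas. Splits that call that many genes point to a structure of the samples other than the labelled groups. Splits that parted as many pairs from 1 dam as the real one gave at most 0 genes, in 12 splits of controls and 6 of HEamiRNA placentas, while the others put both placentas of some dams on 1 side.

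The 42 genes of the authors' table came back with DESeq2 on 19 placentas. With the treatment reassigned over the 11 dams, 16 of 60 splits gave at least as many genes, with 883 at most, so chance cannot be excluded, and such a split points to a structure of the samples. Counting placentas of 1 dam as independent may explain part of the count, since DESeq2 called 1 gene on counts summed per dam. The tool is another candidate explanation, since edgeR called 0 genes with the same model on the same 19 placentas, where DESeq2 called 42. A response to HEamiRNAs stays open as well, and was not tested on other animals.

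The yolk sac endoderm list was lower in HEamiRNA placentas by camera with the preset correlation only, and its genes rose and fell together within groups. Library size was argued against, with r = 0.230 between score and library total (p = 0.345, n = 19; Spearman rho 0.126). This p counts the 19 placentas as independent, although 8 dams gave 1 placenta of each sex. Varying amounts of yolk sac tissue in the samples may explain the pattern, since the median correlation between pairs of its 16 genes within groups was 0.947 (0.602 to 0.998, 120 pairs), and Afp reached 11330 CPM in HEamiRNA Female 6. Genes regulated together in the same cells would also correlate, so this cannot tell tissue amount from regulation. The slopes of single genes on the list mean ran from 0.484 to 1.45, so the size of the changes differed between genes. The scores of the dams overlapped (7.39 ± 0.677 against 7.67 ± 0.761, exact permutation p = 0.513, n = 6 and 5, without the male-share covariate), so spread between dams may suffice. An effect of HEamiRNAs on these cells stays open.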

How the results depend on the processing

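Fits without the libraries of doubtful sex-linked counts, a yolk sac covariate, the permutation of list scores, the alternatives for the lists of the sex comparisons and the refits of the authors' table were chosen after the data were seen. The count of 0 genes by edgeR was kept in males under 23 of 23 alternatives and for the interaction under 30 of 30, with 718 and 239 genes at an unadjusted p under 0.05. It was kept in females under 20 of 22, per dam under 24 of 26, for sex in controls under 19 of 21 and in HEamiRNA placentas under 19 of 22 (unadjusted 748, 688, 433 and 211). The exceptions follow, and the cause was not tested unless stated. With a replicate block, 27 genes passed in females (0 higher, 27 lower; Alb -3.56, Fga -2.50, Ttr -1.80), 525 for the treatment effect per dam (100 higher, 425 lower) and 3 for sex in HEamiRNA placentas. In the treatment comparisons this block joined control and HEamiRNA dams of equal number, which are different animals. Numbers found in 1 treatment only cannot inform such a fit, so HEamiRNA dam 6 did not count per dam. In females only numbers 1, 3 and 4 occur in both treatments. Without a block, the yolk sac mean went from -0.49 to -1.07 per dam when HEamiRNA dam 6 was left out. In females it went from -0.58 to -1.725 without HEamiRNA Female 6. The effect of the block apart from these losses was not tested. With DESeq2, 1 gene passed per dam. Without the 3 libraries against their sex label, 8 genes passed for sex in controls and 13 in HEamiRNA placentas, since these 3 had Y-linked counts near those of the other label. Without those 3 and the 2 intermediate libraries the numbers were 11 and 10, and 1 gene passed in females. The refit of the authors' model called 42 genes where edgeR called 0. Lists passing fell to 0 with an estimated correlation and with fry in males, females, per dam, for the interaction and for sex in controls and HEamiRNA placentas, and to 0 with the permutation of list scores, which was not run for the interaction. With 126 to 462 possible splits per comparison, 1 list alone could not pass this permutation after adjustment over 29 lists, so its count of 0 says little. For sex the lists passing also fell to 0 in both treatments with a replicate block and an estimated correlation, and with exact sign flips within dams, while the block alone gave 18 in controls and 9 in HEamiRNA placentas. With DESeq2 size factors they numbered 13, 15, 18 and 6, and with library totals alone 12, 17, 18 and 8. Leaving out 1 library or dam gave 10 to 15 lists in males, 9 to 15 in females (9 without Control Female 1), 14 to 21 per dam and 3 to 12 for the interaction. For the interaction there were 3 without Control Female 1, 10 without Control Female 2, Control Female 3, Control Male 4 or HEamiRNA Female 3, 11 without Control Male 1 or HEamiRNA Female 1, and 12 without HEamiRNA Male 1. For sex there were 11 to 17 in controls and 6 to 16 in HEamiRNA placentas (16 and 6 with all libraries), with 10 without HEamiRNA Male 1, 11 without HEamiRNA Male 4, and 16 without HEamiRNA Female 3 or without the 3 libraries against their sex label. Over these fits the mean log2 fold change changed sign for extracellular matrix in males (-0.25 to 0.0493, highest without Control Male 1) and per dam (-0.30 to 0.00476, highest without control dam 1). It did so for ribosomal proteins in females (-0.17 to 0.0279, highest without HEamiRNA Female 1) and per dam (-0.11 to 0.0134, highest without HEamiRNA dam 1). Without HEamiRNA Female 3 it did so for spongiotrophoblast in females (-0.17 to 0.27) and for the interaction (-0.32 to 0.13), and for Y-linked genes in females (-2.30 to 9.26) and for the interaction (-9.45 to 2.11). For sex in HEamiRNA placentas it did so for oxidative phosphorylation (-0.0171 to 0.0537, lowest without HEamiRNA Female 1). Without the 3 libraries the spongiotrophoblast mean in females was -0.0363. Among the other values, 4055 kept direction and side of the threshold, 223 no longer passed, 34 newly passed and 206 moved by more than the bound set for them. Depth was 39864554 to 61371498 counts per library, and genes under the low-count filter were left untested. At this depth, 1.5-fold changes simulated without correlation between genes were recovered for 46.3% of genes in males and 28.4% for the interaction.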

Other observations

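The search for jumps of single libraries was chosen after the data were seen, while the test of Xist against decidual genes was chosen before its result.

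In the sex comparisons, further lists passed camera with the preset correlation. None of these passed with an estimated correlation, where their adjusted p lay between 0.397 and 0.565 in controls and was 0.408 and 0.888 in HEamiRNA placentas. In controls, lower in males were endothelium (mean log2 -0.15, 16 of 17 genes), cell cycle (-0.20, 24 of 28), nutrient transporters (-0.07, 18 of 23), imprinted genes (-0.10, 21 of 25), syncytiotrophoblast (-0.18, 10 of 12), interferon response (-0.10, 20 of 26) and macrophages (-0.15, 11 of 14). Higher in males were spongiotrophoblast and glycogen cells (0.16, 23 of 26 genes), unfolded protein and stress response (0.09, 15 of 19), inflammatory cytokines (0.14, 10 of 12) and epithelial-mesenchymal transition (0.05, 21 of 32). In HEamiRNA placentas, stratified epithelium and amnion (0.85, 8 of 9 genes) and oxidative phosphorylation (0.03, 34 of 46) were higher in males. Once the 3 libraries against their sex label were left out, interferon response (-0.0766), inflammatory cytokines (0.134) and epithelial-mesenchymal transition (0.0182) in controls and stratified epithelium (0.63) in HEamiRNA placentas no longer passed. With the dam as a replicate block, epithelial-mesenchymal transition (0.0533) in controls and stratified epithelium (0.41) and oxidative phosphorylation (0.0322) in HEamiRNA placentas no longer passed. Leaving out 1 control library ended calls without Female 1 (spongiotrophoblast 0.0416, macrophages -0.0249, imprinted genes -0.0646, unfolded protein 0.00391), Female 2 (transition 0.0247), Female 3 (transition 0.0157, interferon -0.0795), Female 5 (transition 0.0183, interferon -0.067, cytokines 0.113), Male 1 (syncytiotrophoblast -0.13, cytokines 0.0543, transition 0.0337), Male 3 (syncytiotrophoblast -0.109, imprinted -0.0618), Male 4 (transition 0.00958, unfolded protein 0.0307, cytokines 0.0573, macrophages -0.159, interferon -0.0967) and Male 5 (macrophages -0.0436, interferon -0.0595). Other means moved by more than 1.5 times with the call kept: spongiotrophoblast to 0.28 without Female 3, 0.26 without Male 5 and 0.105 without Male 3, macrophages to -0.23 without Male 1, transition to 0.0999 without Female 1 and 0.0814 without Male 5, and cytokines to 0.25 without Male 5. Interferon moved to -0.155 without Male 3 and -0.166 without Female 4, nutrient transporters to -0.0493 without Male 1, -0.121 without Female 3, -0.123 without Male 4 and -0.115 without Male 5, imprinted genes to -0.147 without Female 3, and unfolded protein to 0.0561 without Female 2 and 0.135 without Female 3. In HEamiRNA placentas the stratified epithelium mean was 0.446 without Male 2 and 1.39 without Female 1. Oxidative phosphorylation lost its call without Female 1 (-0.0171), Male 4 (0.0174) and Female 6 (0.0427), and was at 0.0536 without Female 3 and 0.0537 without Female 4. Whether the sex difference itself differed between treatments is the interaction given above.

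Placentas labelled male with matching Y-linked counts had Xist at 97.9 to 335 CPM (n = 8). RNA of maternal cells is a candidate explanation. Xist had r = 0.449 with the decidual stroma score over these 8 libraries (exact permutation p = 0.171, Spearman rho 0.238, exact permutation p = 0.582), and r = -0.117 without the 2 farthest points, so this test left it open. The dissection would have removed the decidual part, and the decidual genes may also be expressed by other cells of the placenta.

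Within groups the yolk sac endoderm score had r = 0.548 with the stratified epithelium and amnion score (p = 0.0148, adjusted over 6 relations 0.0596, n = 19; Spearman rho 0.661, r without the 2 farthest points 0.614). With the spongiotrophoblast and glycogen cell score it had r = -0.512 (p = 0.0199, adjusted 0.0596; rho -0.272, r without the 2 farthest points -0.239). With syncytiotrophoblast r was 0.363 (adjusted p 0.205, n = 19) and with decidual stroma -0.364 (adjusted p 0.205). The permutations behind these p moved the 19 placentas freely, although 8 dams gave 1 placenta of each sex. The p may therefore be too small. The first principal component held 28.5% of the variance and had r = -0.955 with the yolk sac endoderm score.

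Of 2826 genes with at least 100 CPM in a library, 9 had a library at 5 times the median of the others or more. In this part CPM use plain totals. Of these genes, 6 lay on chromosome 12 within 250 kb of the 7SL RNA genes Rn7s1 and Rn7s2 (69159295 to 69361481). They were Klhdc2 (1355 CPM in HEamiRNA Male 1, others 38.7 to 82.9), Rpl36al (488 in Control Male 1, others 14.1 to 115), Lrr1 (2567 in Control Female 1, others 0.339 to 1192), Mgat2 (585 in HEamiRNA Male 3, others 37.7 to 124), Nemf (4784 in HEamiRNA Male 6, others 154 to 3699) and Arf6 (644 in Control Male 4, others 79.0 to 279). The other 3 were highest in HEamiRNA Male 6: Hsd3b1 (361 CPM, others 5.07 to 298), Alb (480, others 9.53 to 343) and Slc39a8 (266, others 19.9 to 186).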
